A study of Mus musculus with 12 samples.

How the data were processed

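RNA of 4 groups of mouse cells, 3 arrays each, was labelled with biotin by an Affymetrix whole-transcript kit, per the labels' protocols. The iPS and ES cells were grown on feeder fibroblasts treated to stop division, and per the labels' protocols the ES cell suspension was plated briefly so that feeders would settle out before RNA was extracted. The table used is the value table that the authors deposited for the whole series, with log2 values per probe set. It names no scale, and log2 was taken from the range, 2.43 to 13.64. How the authors summarised and normalized the arrays is not given in the sources used here. The medians of the 12 arrays lie between 7.89 and 8.29 and are not centred, and values are absolute levels with no ratio direction to settle.

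The table holds 10360 probe sets. Each varies at least 1.42-fold, or 0.51 on the log2 scale, between its lowest and highest array, and 70.4% have group means that differ by over 1 on the log2 scale. A filter on variation before deposit would leave such a table, and its criterion is not given in the sources used here. Adjusted p-values, list tests and shares of genes therefore refer to these varying genes, and list members absent from the table were not analysed here. Probe sets were named from the platform annotation: 9542 had 1 gene symbol, 344 had several and 474 had none, and only the first kind was tested. Of the gene identifiers, 9533 matched the current gene table, and 0 symbols needed an update. For the 3 genes with over 1 probe set, the probe set with the highest mean over all arrays was used, which left 9539 genes. No build is named, so no coordinates are given.

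Differences were tested in R 4.3.3 with limma 3.58.1, with a mean per group over all 12 arrays, eBayes with its default prior and Benjamini-Hochberg adjustment over the 9539 genes of a comparison. A call needs an adjusted p under 0.05 and an absolute log2 difference of at least 1, and every adjusted p in the text comes from limma. The 5 comparisons, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Of 28 gene lists, 22 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. With an estimated correlation the pluripotency list alone kept its call, in the comparisons of iPS cells with fibroblasts, of ES cells with fibroblasts and of iPS cells with day-1 cells. The counts of called members adjusted over the list alone equalled those over all genes for every list and comparison. Fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, passed for 15, 20, 22, 13 and 20 of the 22 lists in the order day-1 cells, iPS cells and ES cells against fibroblasts, iPS against ES cells, and iPS against day-1 cells.

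Named genes were chosen by a rule: per comparison, the 10 highest and 10 lowest differences among called genes whose groups do not overlap, leaving out unnamed gene models; up to 4 called members per list by size, or up to 2 members with the highest mean where none was called; and always Pou5f1, Tet1, Sox2, Klf4, Myc and Nanog. The text prints part of what the rule yields. Members that are the exceptions in a list count, or that complete such a count, are named beyond the rule, after their values were seen.

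The steps were tested on simulated data with the real means and spreads of the 9539 genes, of which 200 were changed. In the simulated day-1 comparison, 100% of genes changed by 1.5 on the log2 scale and 58% of those changed by 1 were called, and 0 of 9339 unchanged genes. In the simulated comparison of iPS with ES cells the shares were 100% and 66%, again with 0 of 9339. For lists of 20 genes in the day-1 comparison, a shift of 0.5 was found in 20 of 20 runs and an unshifted list in 1 of 20. In the list runs no gene outside the shifted list was changed, while 5449 of 9539 genes had a limma adjusted p under 0.05 in the real day-1 comparison. Camera compares a list with the other genes, so these runs do not show how often it finds such a shift among changed genes. Simulated genes varied independently of each other, so the list runs do not test the list calls where genes are correlated either. The alternatives were quantile normalization, arrays centred on the common median, leaving out the lowest 25% of genes by mean, averaging or testing every probe set of a gene, fitting only the groups compared, a trended robust prior, array weights, a replicate block, no fold minimum, limma's treat and leaving out each array. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.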

Results

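Gene expression was measured on 12 Affymetrix arrays in mouse cells at successive stages of reprogramming by Oct4, encoded by Pou5f1, and Tet1, an enzyme that oxidises methylated cytosine in DNA. The labels give 4 groups of 3 arrays. Fibroblasts were at passage 3. Day-1 cells were fibroblasts at passage 3 that came from mice made with Oct4 and Tet1 iPS cells, and had spent 1 day in ES medium with doxycycline, the drug that switches the factors on. The iPS cells were a line at passage 10 made with the same factors, and the ES cells were the R1 line at passage 20. The ES cells have another strain background than the other 3 groups, and both pluripotent lines grew on feeder fibroblasts. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples. The median log2 value of an array lay between 8.25 and 8.29 in fibroblasts and day-1 cells, between 7.98 and 8.06 in iPS cells and between 7.89 and 7.98 in ES cells. Arrays of one group correlated across genes with r between 0.988 and 0.997. The correlation was 0.927 to 0.944 between fibroblasts and day-1 cells, 0.942 to 0.950 between iPS and ES cells, and 0.546 to 0.589 between fibroblasts and ES cells. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.09.

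The induced factors come first. Pou5f1 had a log2 value of 5.04 ± 0.18 (SD, n = 3) in fibroblasts, 11.79 ± 0.06 in day-1 cells, 12.01 ± 0.04 in iPS cells and 12.36 ± 0.00 in ES cells. Its level in day-1 cells was 108-fold above that in fibroblasts, a log2 difference of 6.76 ± 0.08 (SE; limma adjusted p = 1.6e-14). Tet1 had 6.68 ± 0.17 in fibroblasts, 7.46 ± 0.02 in day-1 cells, 10.25 ± 0.08 in iPS cells and 11.36 ± 0.10 in ES cells. Its day-1 difference of 0.79 ± 0.09 had an adjusted p of 8.4e-06 and stayed under the 2-fold minimum set for a call. The sources used here do not say whether a probe set reads the introduced copy, the endogenous transcript or both.

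**Figure D1:**
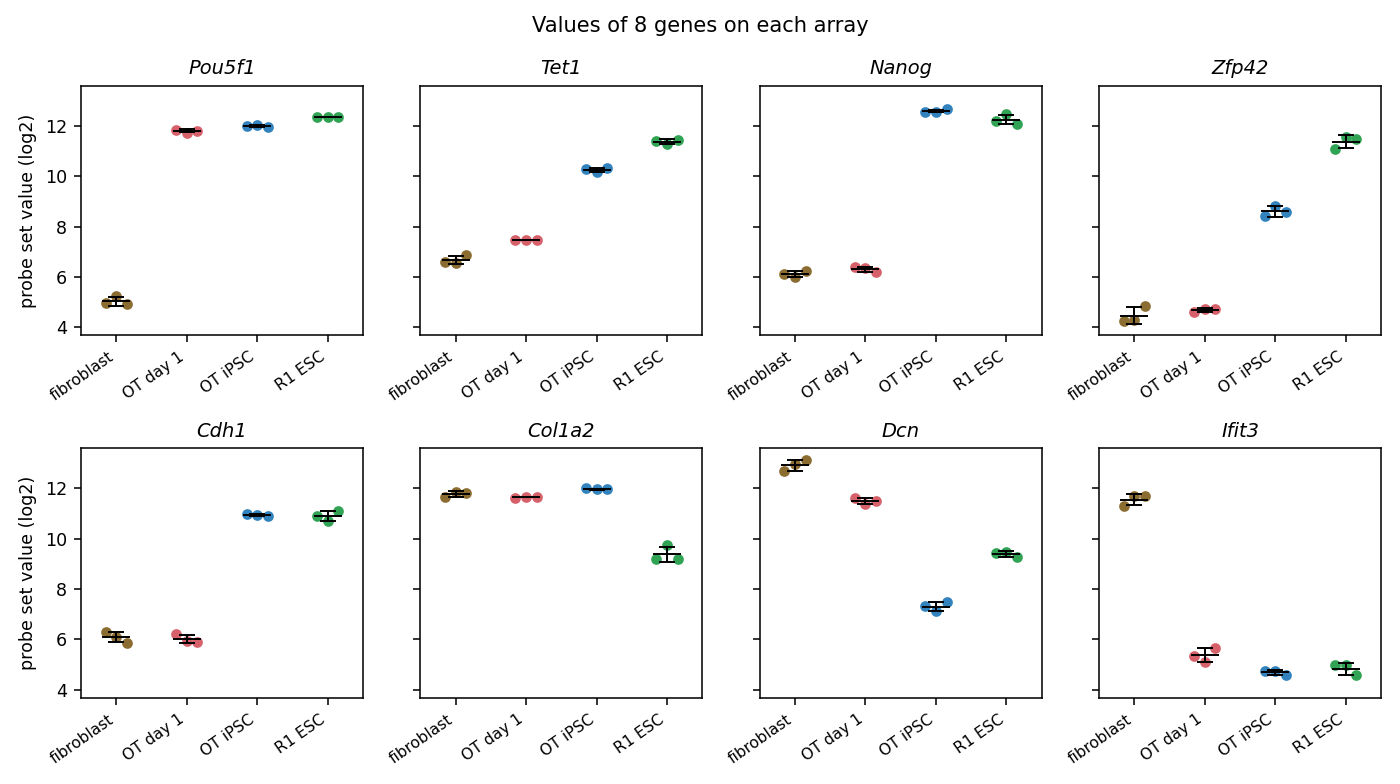
Log2 probe set values of 8 genes on each of the 12 arrays, in columns for fibroblasts, day-1 cells, iPS cells and ES cells, with the group mean (dash) and SD (bar). Pou5f1 has a mean of 11.79 in day-1 cells, while Nanog has 6.31 there and 12.59 in iPS cells, and Dcn is lower in iPS cells (7.31) than in ES cells (9.39).

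The first comparison asks what differs between day-1 cells and fibroblasts, with doxycycline, the change of medium and the source of the fibroblasts differing together. In day-1 cells, cell cycle genes were higher and genes of the interferon and inflammatory responses were far lower, while no gene of the pluripotency network other than Pou5f1 was called. Of 9539 genes, 743 were called, 330 higher and 413 lower. Without the dimmest 25% of genes, 248 were lower, and the share of higher calls was 52.2% against 44.4%. All 20 measured G2/M genes rose, among them the mitotic kinesin Kif11 (log2 difference 1.74 ± 0.11, SE), the mitotic kinase Plk1 (1.73 ± 0.11) and cyclin A2, Ccna2 (1.70 ± 0.09). Of 24 S-phase genes, 17 rose and 7 did not pass, with Mcm5 of the replicative helicase at 1.74 ± 0.09 and the chromatin assembly factor Chaf1b at 1.69 ± 0.09. The adjusted p of camera, limma's list test, was 3.0e-13 for G2/M genes and 5.5e-13 for S-phase genes, and 0.13 for both with an estimated correlation.

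Of 15 interferon response genes, 14 fell and Oas1a did not pass (-0.97). Ifit3 differed by -6.18 ± 0.15, Ifit1 by -5.34 ± 0.27, the chemokine Cxcl10 by -4.70 ± 0.20 and Oasl2 by -4.66 ± 0.22. Of 14 inflammatory genes, 12 fell, led by the acute-phase protein Saa3 (-7.28 ± 0.23) and by Lcn2, which binds bacterial siderophores (-6.39 ± 0.12). Ptgs2 (-0.19) and Csf1 (-0.13) did not pass. Camera gave an adjusted p of 5.5e-13 for the interferon list and 3.7e-11 for the inflammatory list, and 0.13 and 0.12 with an estimated correlation. The median level of the interferon list was 10.49 in fibroblasts, 6.38 in day-1 cells, 6.19 in iPS cells and 6.12 in ES cells, and the fibroblasts stood apart from the other 3 groups. Of 10 macrophage markers, 3 fell, Adgre1 (3.99-fold lower), Cd14 (-1.54 ± 0.11) and Lyz2 (-1.03 ± 0.15, a call that ended under 3 settings), and C1qb rose (1.48 ± 0.12). The list as a whole had an adjusted p of 0.57.

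In the pluripotency list, Pou5f1 was the sole member called in day-1 cells, and 23 of the 26 members had a 95% interval within 2-fold. At an unadjusted p under 0.05, 9 members, Pou5f1 included, were higher and 2 lower. The list had a camera adjusted p of 0.28 and was higher by fry (adjusted p = 1.0e-05). Pou5f1, itself induced, counts in both tests with its difference of 6.76, against a list mean of 0.38 and a median of 0.18. The list was not tested without Pou5f1, so the fry result does not show a rise of the other members. Nanog differed by 0.18 ± 0.10 (adjusted p = 0.14) and Sox2 by -0.17 ± 0.17 (adjusted p = 0.41), and both factors stood near 5 to 6 on the log2 scale in both groups. Klf4 (-0.54 ± 0.10) and Myc (0.11 ± 0.13) were not called. Of 19 genes on the glycolysis list 10 were measured, and Aldoa, Gapdh, Pgk1, Pkm and Ldha were among those absent from the table. The measured members were lower as a list (camera adjusted p = 1.9e-04, and adjusted p = 0.13 with an estimated correlation). The 2 of 10 members called were Pdk1, a kinase that inhibits pyruvate dehydrogenase (-1.88 ± 0.13), and the phosphofructokinase Pfkl (-1.10 ± 0.07). In the list of p53 and senescence genes, 8 of 17 were measured, without Cdkn1a, Mdm2 and Trp53. Of the 8 measured, 2 fell, Trp53inp1 (-1.36 ± 0.08) and the cell cycle inhibitor gene Cdkn2a (-1.27 ± 0.07). The list adjusted p was 0.013, and the adjusted p was 0.13 with an estimated correlation. Contractile genes rose in 3 of 15 cases, Ankrd1 (1.94 ± 0.29), Actg2 (1.43 ± 0.16) and Myh11 (1.35 ± 0.10). Their list adjusted p was 0.018, and the adjusted p was 0.74 with an estimated correlation. Of 18 epithelial genes limma called 0, with 6 at an unadjusted p under 0.05, and of 15 Polycomb genes 0, with 10. Neither list was shifted by camera (adjusted p = 0.41 and 0.075), while fry gave an adjusted p of 0.065 and 3.3e-07, with Polycomb genes higher. Of all 9539 genes, 5449 had an adjusted p under 0.05 at day 1, so counts of members at an unadjusted p under 0.05 alone show no shift. The fibroblast matrix list had an adjusted p of 0.20, and 2 of its 28 members fell, Dcn (-1.42 ± 0.12) and Pdgfra (-1.16 ± 0.12).

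After Pou5f1, the genes with the highest differences in day-1 cells were the fatty acid carrier Fabp7 (3.47 ± 0.13), the gap junction gene Gjb2 (3.08 ± 0.19), the tubulin Tuba8 (2.71 ± 0.15), the neurofilament gene Nefl (2.66 ± 0.14), Map2 (2.62 ± 0.10), Socs2 (2.61 ± 0.08), the amino acid transporter Slc38a4 (2.45 ± 0.11), Serpina3n (2.38 ± 0.26) and the intermediate filament gene Nes (2.35 ± 0.14). Also among the 10 lowest differences were Ccl3 (-5.37 ± 0.13), Steap4 (-4.94 ± 0.22), the copper carrier Cp (-4.81 ± 0.17) and the eosinophil chemokine Ccl11 (-4.67 ± 0.18). The count of calls depended on the fold rule: limma gave 5449 genes by adjusted p alone and 315 when the test itself required a difference over 2-fold.

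The second comparison sets iPS cells against fibroblasts, the end point against the starting cell type. All 26 measured genes of the pluripotency network were higher in iPS cells (camera adjusted p = 1.1e-10; adjusted p = 0.033 with an estimated correlation). Dppa5a differed by 7.67 ± 0.33, the Nodal co-receptor gene Tdgf1 by 7.41 ± 0.08, the nuclear receptor gene Nr0b1 by 7.38 ± 0.10, Sox2 by 6.52 ± 0.17 and Nanog by 6.47 ± 0.10. Of 18 epithelial genes, 14 rose, including Epcam (5.09 ± 0.21) and E-cadherin, Cdh1 (4.85 ± 0.12), and Cdh3 fell (-1.02). Of 12 regulators of epithelial-mesenchymal transition, 10 fell, with Twist2 at -5.02 ± 0.10, Snai2 at -3.43 ± 0.08 and Snai1 at -3.33 ± 0.14, and 21 of 28 fibroblast matrix genes fell, with Dcn at -5.62 ± 0.12 and Lum at -4.97 ± 0.21. The adjusted p of the epithelial, transition and matrix lists was 8.2e-05, 0.0016 and 8.8e-05, and 0.19, 0.27 and 0.31 with an estimated correlation.

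Growth and chromatin genes moved in iPS cells too. Of the S-phase list, 21 of 24 genes rose, with the chromatin remodeller Hells at 4.38 ± 0.13 and Mcm3 at 3.98 ± 0.12, and of the G2/M list 17 of 20, with Bub1b at 3.18 ± 0.07. The adjusted p was 1.5e-08 and 3.4e-07, and 0.19 and 0.20 with an estimated correlation. Of 14 genes of DNA methylation and demethylation, 10 rose, among them Dnmt3l (4.71 ± 0.10), Uhrf1 (3.71 ± 0.12) and Dnmt3b (11.3-fold), and Tet3 fell (-1.45). Of 15 Polycomb genes, 9 rose, with Mtf2 at 3.05 ± 0.09 and Cbx7 at 2.64 ± 0.13, and Phc2 fell (-1.21). Germline genes silenced by DNA methylation in somatic cells rose in 11 of 13 cases, among them Hormad1 (2.96 ± 0.25), Dazl (2.38 ± 0.21) and Ddx4 (2.34 ± 0.15). Of 19 on that list 13 were measured, with list means of 4.68 to 4.74 on fibroblast arrays and 4.77 to 4.83 on day-1 arrays. A filter on variation would leave out members low in all groups. Against fibroblasts or day-1 cells, neither the count nor the list test can therefore tell how often germline genes rise. The adjusted p of the DNA methylation, Polycomb and germline lists was 0.0064, 0.0022 and 0.0016, and 0.17, 0.090 and 0.20 with an estimated correlation. Hox genes fell in 17 of 25 cases, with Hoxc6 at -3.02 ± 0.14 and Hoxd10 at -2.88 ± 0.11 (adjusted p = 3.6e-04; adjusted p = 0.13 with an estimated correlation). The list of primed and lineage genes had 6 of 9 members higher, led by Lefty2 (4.99 ± 0.23) and Nodal (3.86 ± 0.11), and Gata6 lower (-1.16). Its adjusted p was 0.021, and 0.17 with an estimated correlation, and its call ended when the dimmest 25% of the genes were left out (adjusted p = 0.14).

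The 5 lowest differences in iPS cells were those of Ppbp (-7.82 ± 0.13), Cxcl5 (-6.87 ± 0.10), Ifit3 (-6.86 ± 0.15), Lcn2 (-6.51 ± 0.12) and the matrix protease Mmp3 (-6.39 ± 0.15). Of the inflammatory list 13 of 14 fell, and of the interferon list 14 of 15. Their adjusted p was 8.2e-05 and 3.6e-04, and 0.17 and 0.27 with an estimated correlation. Among macrophage markers, 6 of 10 fell, led by Lyz2 (-4.59 ± 0.15), and Laptm5 rose (2.61 ± 0.12), with a list adjusted p of 0.15. Contractile genes (1 higher and 5 lower of 15), glycolytic genes (4 and 2 of 10) and p53 genes (1 and 5 of 8) were not shifted as lists, with an adjusted p of 0.11, 0.15 and 0.10. In all, 4897 genes were called, 2075 higher and 2822 lower. The median difference of all genes was -0.35, and 42.4% of calls were higher, against 55.9% when each array was centred on a common median and 52.0% after quantile normalization, so the balance of higher and lower calls is a matter of scaling. List tests compare each list with the other genes and are relative to that shift.

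**Figure D2:**
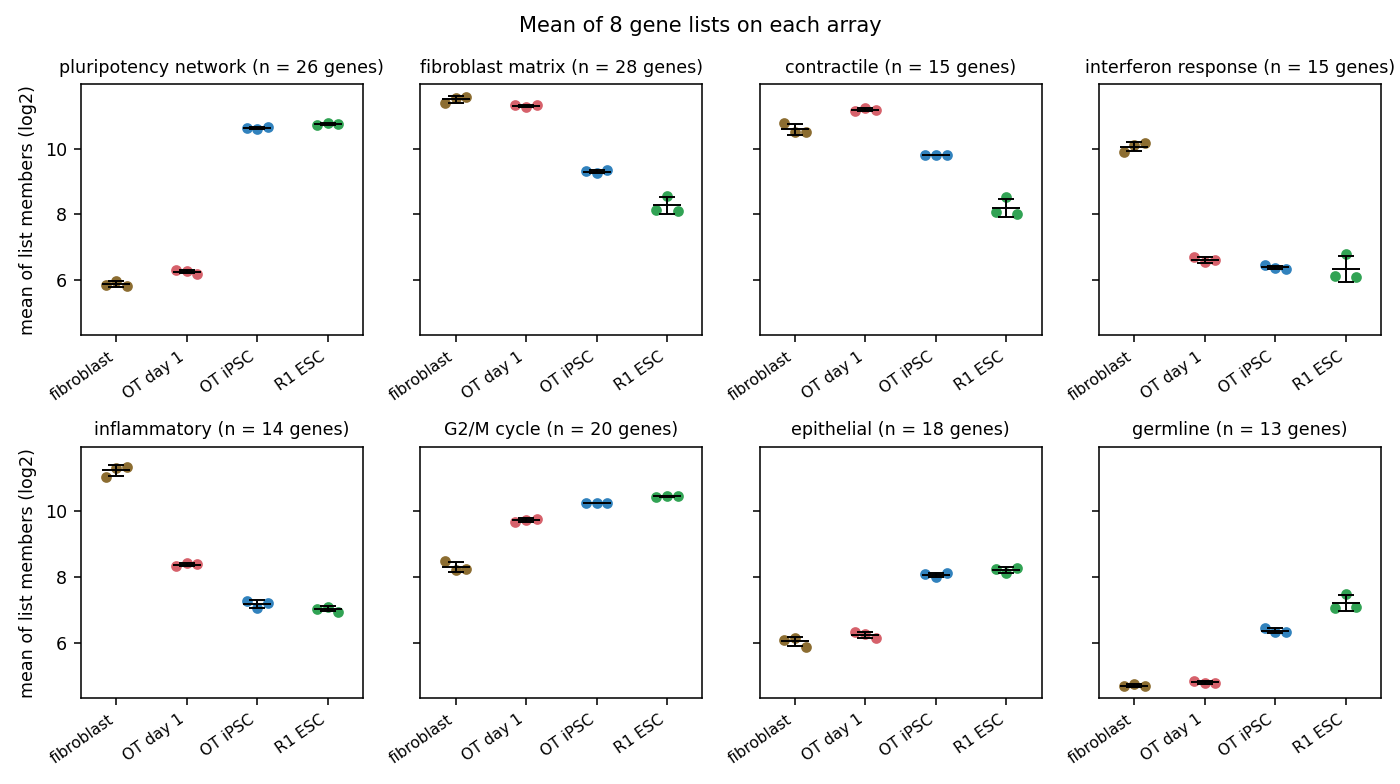
Mean log2 value of the measured members of 8 gene lists on each of the 12 arrays, with the group mean (dash) and SD (bar). The fibroblast arrays lie between 9.90 and 10.16 for the interferon list, against 6.11 to 6.80 in ES cells, and ES replicate 2 has the highest ES mean for the matrix, contractile, interferon and germline lists.

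ES cells against fibroblasts give the reference for a pluripotent line. Here 25 of 26 pluripotency genes rose, Tbx3 not passing (0.92), with a camera adjusted p of 6.2e-10 and an adjusted p of 0.041 with an estimated correlation. Tdgf1 differed by 7.71 ± 0.08, Nr0b1 by 7.53 ± 0.10, Dppa5a by 7.41 ± 0.33 and Zfp42, also known as Rex1, by 6.92 ± 0.16. Of the 28 matrix genes, 27 fell, Fap not passing (-0.72), with Postn at -5.68 ± 0.24 and the collagen cross-linking enzyme Lox at -4.62 ± 0.27, and 12 of 15 contractile genes fell, with Myl9 at -4.39 ± 0.12 and Cnn1 at -4.38 ± 0.17. The adjusted p was 4.5e-07 for the matrix list and 0.0025 for the contractile list, and 0.25 and 0.35 with an estimated correlation. All 12 transition regulators fell, with Zeb2 at -3.87 ± 0.07, and 14 of 18 epithelial genes rose, with Esrp1 at 3.98 ± 0.11. Their adjusted p was 2.8e-04 and 6.8e-05, and 0.25 and 0.17 with an estimated correlation. Germline genes rose in 12 of 13 cases, with Mael at 4.01 ± 0.10 and Sycp3 at 3.99 ± 0.13 (adjusted p = 2.4e-04, and 0.17 with an estimated correlation). The limit that a filter on variation sets for this list holds here too. All 14 inflammatory genes and 14 of 15 interferon genes fell, as did 6 of 10 macrophage markers, led by Lyz2 (-5.39 ± 0.15), while Laptm5 rose (2.53) and the macrophage list was not shifted (adjusted p = 0.22). The inflammatory and interferon lists had an adjusted p of 7.2e-05 and 4.2e-04, and 0.17 and 0.26 with an estimated correlation. S-phase genes rose in 20 of 24 cases and G2/M genes in 18 of 20 (adjusted p = 4.0e-08 and 4.5e-07; adjusted p = 0.17 and 0.23 with an estimated correlation). Hox genes fell in 16 of 25 cases, Polycomb genes rose in 10 of 15, with Phc2 lower (-1.20), and genes of DNA methylation in 10 of 14, with Tet3 (-1.51) and Gadd45g (-2.17) lower (adjusted p = 1.9e-04, 0.0024 and 0.0050; adjusted p = 0.11, 0.094 and 0.17 with an estimated correlation). Of the primed and lineage list 6 of 9 rose (adjusted p = 0.014; adjusted p = 0.14 with an estimated correlation), a call that ended without the dimmest 25% of genes (adjusted p = 0.16). Of 5299 calls, 2234 were higher and 3065 lower. The share of higher calls was 42.2%, against 58.7% with centred arrays and 53% after quantile normalization.

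Day-1 cells and ES cells were both compared with the same 3 fibroblast arrays, and those changes were set against each other. Of the genes called in day-1 cells, 187 were higher in both comparisons and 304 lower in both, where independent lists would share 77.3 and 132.7. In opposite directions were 45 genes higher at day 1 and lower in ES cells and 18 the other way, against 106 and 96.7. Across the 9539 genes, which are not independent replicates, r was 0.438 and the covariance 0.468. In 100 simulations of unchanged groups, the shared fibroblast arrays were also drawn from the spread of each gene. The simulations gave a mean r of 0.500 and a mean covariance of 0.00708, and the real covariance was 0.461 above that. Sharing controls of like spread puts the r of unchanged groups near 0.500 by design, so the correlation decides nothing. Spread between arrays is all that was simulated, and a state of the fibroblast cultures that enters both differences was not covered. With 3 fibroblast arrays no split into parts of at least 2 arrays exists, and part of the overlap may come from the shared arrays.

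The comparison of iPS cells with ES cells asks how the reprogrammed line stands to an established one, with strain, passage and line differing together, and with a step to clear feeders that the labels state for ES cells only. Fibroblast matrix and contractile genes were higher in iPS cells, several germline genes were lower, and most of the pluripotency network lay within 2-fold. Of 28 matrix genes, 14 rose, among them Lox (3.03 ± 0.27), Postn (2.74 ± 0.24) and the collagen genes Col1a2 (2.60 ± 0.12) and Col5a2 (2.44 ± 0.12), while Dcn fell (-2.08 ± 0.12) and 13 were not called. Of 15 contractile genes, 12 rose, including Actg2 (3.08 ± 0.16), smooth muscle actin, Acta2 (2.82 ± 0.20), and Cnn1 (2.56 ± 0.17), and of 4 muscle markers Acta1 (1.28 ± 0.17) and Des (1.20 ± 0.09) rose. The adjusted p was 1.3e-06 for the matrix list and 3.0e-06 for the contractile list, and 0.48 for both with an estimated correlation. ES replicate 2 had a matrix list mean of 8.56 against 8.14 and 8.12 on the other ES arrays, and without it 722 genes were called in place of 658.

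In the pluripotency list, Zfp42 was lower in iPS cells (-2.77 ± 0.16), Tfcp2l1 was higher by 1.01 ± 0.13, a call that ended under 5 settings, with centred arrays (0.91) and when any 1 of 4 single arrays was left out, and 24 were not called, 20 of the 26 having a 95% interval within 2-fold. Pou5f1 differed by -0.36 ± 0.08, Nanog by 0.34 ± 0.10 and Sox2 by -0.40 ± 0.17, all under the 2-fold minimum. Tet1 was lower in iPS cells (-1.11 ± 0.09, adjusted p = 5.0e-07), as was Myc (-1.26 ± 0.13). Germline genes fell in 5 of 13 cases, with Mael at -1.96 ± 0.10, the cohesin gene Stag3 at -1.94 ± 0.14, Sycp3 of the synaptonemal complex at -1.74 ± 0.13, Tex11 at -1.44 ± 0.23 and Taf7l at -1.35 (list adjusted p = 0.0028; adjusted p = 0.48 with an estimated correlation). Otx2 was lower (-2.79 ± 0.17), while Lefty2 (1.81 ± 0.23) and Nodal (1.09 ± 0.11, a call that ended with centred arrays) were higher, and the primed and lineage list was not shifted (adjusted p = 0.74). The transition list had an adjusted p of 0.047, with Tgfb3 (2.01 ± 0.20) and Tgfb2 (1.53 ± 0.10) higher and Tgfb1 lower (-1.17 ± 0.08). That call ended with an estimated correlation (adjusted p = 0.68), after quantile normalization (adjusted p = 0.058) and under 6 other settings.

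Among cell cycle genes, limma called 0 of 24 S-phase and 0 of 20 G2/M genes, 6 and 14 had an unadjusted p under 0.05, and all 44 had a 95% interval within 2-fold. Of the G2/M genes, 12 were lower in iPS cells and 2 higher at that unadjusted p. The G2/M list had an adjusted p of 0.054 and was called lower under 4 settings, such as the fit of only the groups compared (adjusted p = 0.022; adjusted p = 0.84 with an estimated correlation). The interferon list had 0 of 15 members called and 5 at an unadjusted p under 0.05, the Hox list 0 of 25 and 9, and macrophage markers 0 of 10 and 1. In this comparison 5502 of all 9539 genes had an adjusted p under 0.05, so such counts of members alone show no shift. Beside the list members, the highest differences in iPS cells were Usp17ld (4.54 ± 0.18), Rps13 (4.36 ± 0.45), Baiap2l1 (4.23 ± 0.07), Ccdc80 (3.93 ± 0.18), the oocyte homeobox gene Obox6 (3.59 ± 0.18) and Nlrp4f (3.58 ± 0.10). The lowest were Mmp3 (-3.87 ± 0.15), Rpl36 (-3.32 ± 0.38) and the neuronal filament gene Ina (-2.95 ± 0.11). Rps13, Rpl36 and Usp17ld have near-identical copies in the genome, so their values are uncertain. Of the 658 calls, 424 were higher and 234 lower in iPS cells, and 8294 genes, 86.9%, had a 95% interval within 2-fold. The share of higher calls was 64.4%, against 51.4% with centred arrays and 57.6% after quantile normalization. Without the dimmest 25% of genes it was 71% with 143 genes lower, and 226 genes passed when the test required a difference over 2-fold.

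**Figure D3:**
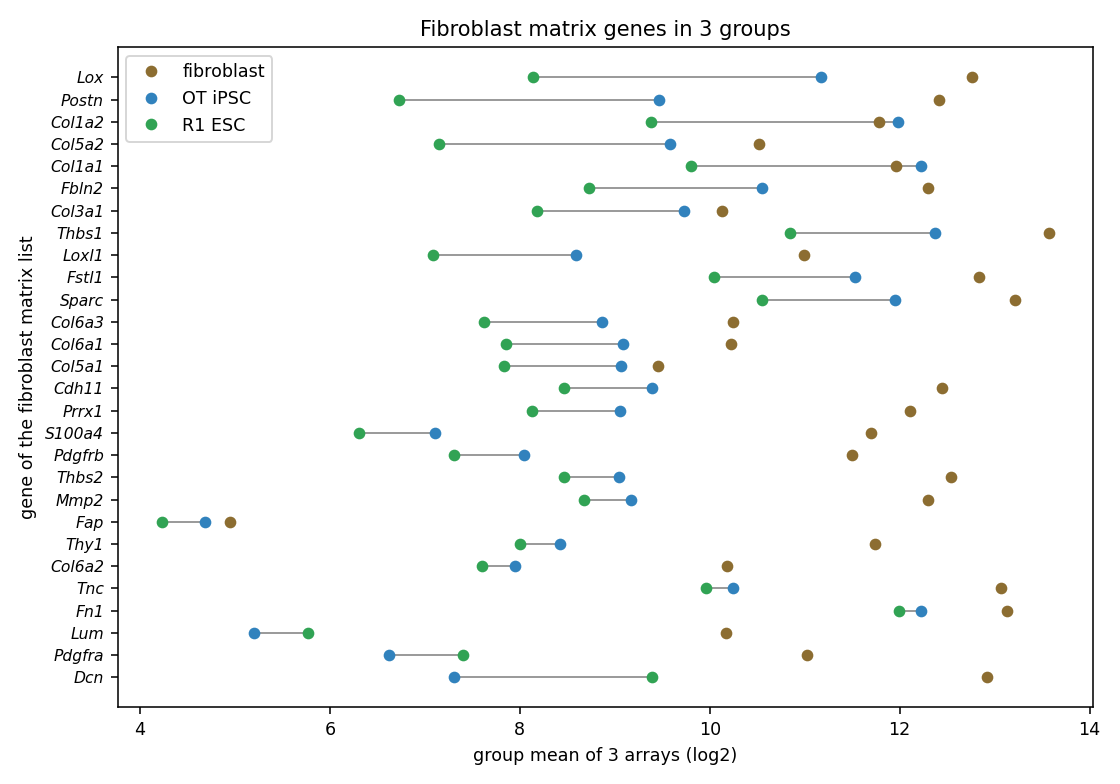
Group means (log2, 3 arrays each) of the 28 fibroblast matrix genes in fibroblasts, iPS cells and ES cells, ordered by the difference between iPS and ES cells, with a line joining both pluripotent groups. Lox is 3.03 higher in iPS cells and Dcn is 2.08 lower (difference -2.08), while both stand highest in fibroblasts.

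Between iPS cells and day-1 cells, 4216 genes were called, 1679 higher and 2537 lower, with 39.8% higher against 55.3% with centred arrays and 51.2% after quantile normalization. Pluripotency genes rose in 25 of 26 cases (adjusted p = 2.9e-11; adjusted p = 0.028 with an estimated correlation), Pou5f1 being the exception (0.21 ± 0.08), and Dppa5a (7.99 ± 0.33), Sox2 (6.69 ± 0.17) and Nanog (6.28 ± 0.10) were among them. Glycolytic genes rose in 6 of 10 cases, led by hexokinase 2, Hk2 (3.13 ± 0.07). Contractile genes fell in 11 of 15, matrix genes in 21 of 28 and transition regulators in 11 of 12. The adjusted p of these 4 lists was 0.0091, 0.0059, 1.7e-04 and 5.0e-04, and 0.31, 0.42, 0.39 and 0.31 with an estimated correlation. G2/M genes rose in 6 of 20 cases and S-phase genes in 14 of 24 (adjusted p = 0.018 and 6.7e-05; adjusted p = 0.51 and 0.32 with an estimated correlation), and the interferon list was not shifted (adjusted p = 0.94). The other 5 shifted lists were the epithelial, germline, Hox, DNA methylation and Polycomb lists. Their adjusted p was 2.0e-04, 0.0016, 6.5e-04, 0.0064 and 0.0091, and 0.29, 0.29, 0.15, 0.21 and 0.15 with an estimated correlation.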

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

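The tests of one common fibroblast share, of iPS or ES levels above the fibroblast level, of macrophage markers and of single fibroblast arrays were chosen after the results were seen. The other tests were set before the data were examined.

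Probe sets that the comparisons leave out, because the annotation gives them no gene symbol or several, also carried signal. Among the 474 without a symbol, limma called 42 in day-1 cells, 235 in iPS cells and 243 in ES cells against fibroblasts. Among the 344 with several symbols it called 53, 172 and 181.

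Of 28 matrix genes 14 and of 15 contractile genes 12 were called higher in iPS than ES cells, Dcn was lower, and the adjusted p of both lists was 0.48 with an estimated correlation; RNA from fibroblasts or feeders in the iPS samples would raise such genes, and 291 of the 424 higher genes (68.6%) were also called higher in fibroblasts than in ES cells, against 32.1% of all genes, an excess that the shared ES arrays can inflate. RNA of cells like the profiled fibroblasts in a common share, as the sole source of the matrix differences, is argued against by the 28 matrix genes. The share each would need had a median of 13.7%, and needs ran from 126% for Col1a1 to -7.16% for Dcn, named after their values were seen. Within 2-fold of the median lay 5 of 28. A first criterion, also written after the data were seen, counted genes over 2-fold below the level that the median share adds; it gave 7 of 28, exactly its own bound, decided nothing, and was replaced by this count and the next one with that outcome and the share of each gene known. Such RNA is also argued against for the 30.9% of the 424 genes (131) whose iPS level lay above the fibroblast level too, since a mix lies between its parts, and stays open for the rest, because adding the median share lifts 35.1% of the 424 genes 2-fold, between the bounds set beforehand of 10% and 50%. The shares take ES cells, also grown on feeders, as free of such RNA, and signal as proportional to RNA. Such RNA together with differences between the lines stays open. The feeders were not profiled, the labels state feeder clearing for ES cells only, and strain, passage and line differ with the groups and were not tested.

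Of the 234 genes lower in iPS than ES cells, RNA of cells like the profiled fibroblasts in the ES samples is argued against for the 73.9% (173) whose ES level lay above the fibroblast level. For the others it stays open, since a share estimated below 0 (-9.36%) fixes the part of these genes explained at 0%, so that the bound set beforehand of under 10% decides nothing, and 17 of the 234, among them Mmp3 and Dcn, were called higher in fibroblasts than in ES cells.

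At day 1, 330 genes were higher than in fibroblasts. Cells like the iPS line mixed into the day-1 samples are argued against, because the 247 of these genes with a higher mean in iPS cells than in fibroblasts would need a median share of 59.8% of the iPS signal, while 25 pluripotency genes without Pou5f1 showed a median of 0.268%. For a handling or array effect common to day-1 and iPS arrays, the differences of day-1 cells from fibroblasts and of iPS from ES cells, which share no array, were correlated. Their r of 0.022 across genes argues only against an effect that dominates both differences. Differences between the cell types also enter that r, so a smaller effect is not excluded. A common part in some genes stays open, since 25 genes were higher in both against 14.7 expected and 29 lower in both against 10.1. In opposite directions, 7 were higher at day 1 and lower in iPS cells against 8.1 expected, and 21 the other way against 18.4. An r of 0.244 in 1435 genes with little difference between ES cells and fibroblasts decides nothing. Choosing genes where both subtracted groups are alike gives both differences a common baseline, which alone can make r positive. Doxycycline, medium and the source of the fibroblasts differ together and may each contribute.

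Interferon and inflammatory genes were lower in day-1 cells than in fibroblasts and stood apart in the fibroblast arrays. A single fibroblast array is argued against, since the interferon list mean of each fibroblast array lay 3.28 to 3.54 on the log2 scale above the day-1 mean. Macrophages in the fibroblast samples stay open: 3 of 10 measured macrophage markers were called lower at day 1 and C1qb, low in fibroblasts, was called higher, while Ptprc, Itgam and 4 other markers were not analysed here. A bound of at least 5 markers lower and none higher was not met, but it was written with that count known and decides nothing. An activated state of the fibroblast cultures, an effect of the medium and an effect of the induced factors stay open as hypotheses, since they differ together.

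Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split was the 1 with the most genes in each comparison: 743 for day-1 cells, 4897 for iPS cells and 5299 for ES cells against fibroblasts, 658 for iPS against ES cells and 4216 for iPS against day-1 cells. The highest other split gave 0 limma calls in each, and at an unadjusted p under 0.05 with the same fold minimum 9, 6, 9, 8 and 1 genes. Each other split mixes both groups in each part, which shrinks the difference and adds it to the spread. Few calls in the other splits therefore follow whenever the groups differ, and these counts do not measure chance.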

How the results depend on the processing

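No called gene changed sign in any comparison under the alternatives for which calls were matched. Counts of calls in both directions together stayed within 1.5 times the reported ones under all alternatives but the fold rules and 1 alternative chosen after seeing the data, while counts of lower genes alone moved further in 2 comparisons. Stable counts hide turnover. With centred arrays, 743 of 743 day-1, 4252 of 4897 iPS and 4499 of 5299 ES calls against fibroblasts were kept. So were 564 of 658 calls between iPS and ES cells and 3568 of 4216 between iPS and day-1 cells, while other genes gained a call. Without a fold minimum the counts were 5449 for day-1 cells, 8985 for iPS cells and 9050 for ES cells against fibroblasts, 5502 for iPS against ES cells and 8851 for iPS against day-1 cells. Requiring a difference over 2-fold in the test gave 315 for day-1 cells against fibroblasts and 226 for iPS against ES cells. Leaving out genes called higher in fibroblasts than in ES cells, the added alternative, left 350 of the 658 calls between iPS and ES cells. With an estimated correlation, the number of shifted lists went from 7 to 0, from 13 to 1, from 14 to 1, from 4 to 0 and from 12 to 1 in that order, where 7, 6, 6, 1 and 4 lists had an unadjusted p under 0.05. Leaving out the dimmest 25% of genes left 2 shifted lists between iPS and ES cells, the matrix and contractile lists, because the germline list no longer had 5 members and the transition list missed the threshold. It also left 248 of 413 lower genes at day 1 and 143 of 234 lower in iPS than ES cells.

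Leaving out 1 array gave 720 to 835 genes for day-1 cells, 4853 to 4917 for iPS cells and 5245 to 5309 for ES cells against fibroblasts, 636 to 722 for iPS against ES cells and 4195 to 4251 for iPS against day-1 cells. Shifted lists then numbered 7, 13, 14 to 15, 3 to 5 and 12. The correlation of day-1 and ES changes was 0.424 to 0.453, and that of the differences sharing no array 0.005 to 0.032. Of 496 pairs of named gene and comparison, 20 lost a call under some setting and 0 reversed. Of the 50 shifts among 110 list results, 47 ended with the estimated correlation, and 3 of those also ended under another setting. A shift was gained under some setting by 3 lists, such as the G2/M list between iPS and ES cells with centred arrays (adjusted p = 0.047). Centring moved the median of all genes by 0, 0.25, 0.35, -0.09 and 0.25 in the order above, and quantile normalization by 0, 0.17, 0.22, -0.04 and 0.17.

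Replicate numbers are shared between groups, but the deviations of same-numbered arrays correlated by -0.177 to 0.083, so the numbers do not pair the samples. With a replicate block the counts were 743, 4897, 5299, 658 and 4216, as without it. Probe sets near the low end of the scale have no stated detection limit, which limits what low levels can show.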

Other observations

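Other lists showed members moving both ways. Among imprinted genes, Plagl1 (2.16 ± 0.16) and Igf2 (1.83 ± 0.21) were higher in iPS than ES cells, while Phlda2 (-1.09 ± 0.10) and Nnat (-1.07 ± 0.11) were lower. That list had a mean of 0.13, a median of -0.31 and a test direction down, and was not shifted (adjusted p = 0.85). At day 1, Mest was higher than in fibroblasts (1.65 ± 0.15), and Meg3 (-1.46 ± 0.10), Rian (-1.27 ± 0.16) and Peg3 (-1.22 ± 0.09) were lower. Immediate early genes also split. Fosb (1.82 ± 0.17) and Fos (2.83-fold) were higher at day 1 and Ier3 lower (-1.71 ± 0.12), and against fibroblasts the list in iPS cells had a mean of -0.06, a median of 0.36 and a test direction up (adjusted p = 0.56). In iPS cells Egr2 (1.74 ± 0.11), Ier3 (1.66 ± 0.12), Egr1 (1.33 ± 0.07) and Jun (1.11) stood above ES cells and Myc below. The list adjusted p was 0.058, and 0.037 with centred arrays, but 0.48 with an estimated correlation. Of 10 genes in the list of LIF and Stat3 targets, 2 were higher in iPS than ES cells, Pim1 (2.83-fold) and Tfcp2l1, and 3 lower, the receptor gene Lifr (-1.30 ± 0.14), Myc and Gbx2 (-1.20). Against fibroblasts, 6 of these 10 were higher in iPS cells and 3 lower, with a list adjusted p of 0.11. Cholesterol genes had 0 of 9 members called at day 1 by limma, with 5 at an unadjusted p under 0.05, where 5449 of all 9539 genes had an adjusted p under 0.05. In iPS cells against fibroblasts, Insig1 (1.39 ± 0.10) and Hmgcs1 (1.13 ± 0.10) rose and Sc5d fell (-1.34 ± 0.10), and Nsdhl fell by 1.04 with its call ending under centring (-0.79). This list had a median of -0.25, a mean of 0.02 and a test direction up (adjusted p = 0.93).

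Markers of further cell types were few in the table. Measured were 5 of 14 keratinocyte, 4 of 13 muscle, 4 of 13 endothelial and 3 of 13 trophoblast markers, and 3 of 14 early cleavage genes. A filter on variation would leave out members that do not change, so counts among the measured ones do not describe the full lists. Of 5 keratinocyte markers, Sfn (2.70 ± 0.14), Krt17 (1.51 ± 0.11) and Perp (1.28 ± 0.12) were higher in iPS cells than in fibroblasts and Ivl was lower, a call that ended under 2 settings, with a list adjusted p of 0.15. In ES cells Sfn (3.01 ± 0.14) and Perp (1.82 ± 0.12) were also higher and Ivl was lower (-1.16 ± 0.14), again a call that ended under 2 settings. Of 4 muscle markers, Des was higher than in fibroblasts at day 1 (1.59 ± 0.09), in iPS cells (3.13 ± 0.09) and in ES cells (1.93 ± 0.09), Tnnt1 in iPS cells (1.69) and Acta1 at day 1 (1.17 ± 0.17). Of 4 endothelial markers, Pecam1 was higher than in fibroblasts in iPS cells (3.96 ± 0.15) and ES cells (3.01 ± 0.15), and Cd34 was lower (-3.79 ± 0.11 and -2.79 ± 0.11). The 3 measured trophoblast markers were called higher in iPS cells than in fibroblasts, with Tfap2c at 2.81 ± 0.15, Eomes at 1.23 ± 0.10 and Gata3 at 1.07 ± 0.15, though the call of Gata3 ended without fibroblast replicate 2 (0.93). In ES cells Tfap2c (2.75 ± 0.15) and Eomes (1.93 ± 0.10) were higher too. Of 3 genes linked to the state of the early cleavage embryo, Tdpoz3 was called higher than in fibroblasts in iPS cells (1.33 ± 0.35) and ES cells (1.29 ± 0.35), the call in ES cells ending without ES replicate 2.

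Of 3 measured sex-linked genes, the Y-linked Eif2s3y had a log2 mean of 7.80 in fibroblasts, 5.87 in day-1 cells, 7.65 in iPS cells and 9.59 in ES cells. Kdm5d, also Y-linked, had 5.85, 6.77, 5.46 and 4.92, a different order of groups. Xist had 4.07, 4.19, 6.24 and 6.11.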
